A study of Homo sapiens with 4 samples.

How the data were processed

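Total RNA of the H9 human embryonic stem cell line from 4 passage groups was profiled on Illumina whole-genome bead arrays, with 1 array per group. Per the labels' protocols, RNA was extracted with Trizol, cleaned up on columns with DNase I treatment, checked on a Bioanalyzer and turned into biotin-labelled cRNA with an Illumina-specific amplification kit. The software used for background subtraction and normalization was not given in the sources used here.

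The deposited values were linear probe intensity values, 47323 probes on each of the 4 arrays. They had been background-subtracted before deposit, as the values themselves show: about 25% of the probes of each array (25.2% to 25.4%) were below 0. The array medians were 17.4 in P1, 17.4 in P2, 17.5 in P3 and 17.4 in P4, the highest values lay between 28270.1 and 30158.8, and the quantiles of the arrays were close but not equal, so a between-array normalization before deposit is apparent without its method being known. A near-common distribution hides any difference in total RNA output between passages, and subtraction makes low values noisy. Bead-level errors and detection p-values were not used here.

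The arrays were quantile normalized. The design, fixed before the data were examined, planned a floor at the 5th percentile for linear data; that percentile was negative (-8.50 in P1) and has no logarithm, so the floor was set to the 60th percentile, 38.4 intensity units, which the design had fixed as the detection limit. Values were then log2 transformed. A gene was represented by its probe with the highest mean over the arrays, and counted as detected in a comparison when at least 1 of the arrays reached the limit. Where a gene was under the limit on the dimmer array, its fold is a lower bound and is given as "at least", a wording added after the data were seen; list medians hold such genes at their bound. Probes were named through the platform's probe annotation, which gave 1 gene symbol for 30113 probes and several for 8, and did not list 17202; 30074 symbols were matched to a current entry by Entrez identifier. This gave 19951 genes, of which 12173 were detected on at least 1 array and 13292 had a lone probe. Probes with several symbols or none were counted and not named. Y-linked genes and transcripts of the X-inactivation centre were not analysed here.

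For each pair of arrays, the log2 difference was taken per gene, and genes at least 2-fold higher or lower were counted. With 1 array per group a pair of arrays has no replicate spread to test against, and the fold rule describes the arrays. A trend of each gene on passage number over the 4 arrays, which leaves 2 residual degrees of freedom, was not fitted. Lists of genes were fixed before the data were examined, 44 in number, of which 43 had at least 3 detected members in P4 against P1. Each list's median log2 difference was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Genes stepping one way through the 4 groups, with a total of at least 2-fold and no minimum for a single step, were counted. The count was set beside those for the other 11 orders of the arrays. Genes were put in chromosomal order with a RefSeq gene table, used for neighbourhood only, and the median of each window of 15 neighbouring detected genes was compared with 200 shuffled gene orders; this window scan was added after the data were seen.

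Named genes started from a rule fixed beforehand. It took the 10 highest and 10 lowest differences of detected genes in P4 against P1, and the 5 highest and 5 lowest in each other pair. It also took the 5 largest steps each way and the 4 members of a described list with the largest difference in P4 against P1. POU5F1, NANOG, SOX2, BCL2L1, TPX2, ID1 and DNMT3B were always named. Ranking only genes measured on both arrays, and on all 4 for the steps, was not in that rule. Genes given as bounds, the list members named in the P3 comparisons, the genes of the plot of levels and those of the closing part outside this rule were chosen after their values were seen.

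The calculation was tested on simulated arrays for P4 against P1, made of 19951 genes with a noise SD of 0.16 log2 units per array. The 2-fold rule called 2.0% of genes changed by 1.5-fold, 82.0% of those changed by 2.5-fold and 100.0% of those changed by 4-fold, and 2 of 11478 unchanged genes. The changed genes, 50 per fold, were drawn from genes detected on all 4 arrays with a mean above 4 times the limit. Their rates therefore do not cover dim genes or folds given as bounds. That noise level was taken from the median absolute deviation between P4 and P3 and is not a replicate spread. The SD over genes was smallest in that pair, at 0.3457 against 0.3925 in P4 against P1. A median absolute deviation also gives little weight to large differences. The simulated counts of unchanged genes called and of stepping genes could therefore be too low. Alternatives tried for the normalization were centring of the arrays on top of quantile normalization, and the deposited values without any. The others were the mean of all probes, no detection filter or the 75th percentile, other fold thresholds, a floor at the 50th percentile, an offset of 50, and means in place of medians. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.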

Results

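The data were whole-genome expression profiles of H9, an established human embryonic stem cell line, in 4 passage groups. One bead array was hybridised with RNA from each passage group, and the groups are called P1 (passages in the 40s), P2 (the 100s), P3 (the 200s) and P4 (the 300s). The design asks how gene expression of the line differed between early and late passages. Each group had 1 array and there were no replicates, so each difference compares 2 arrays and has no replicate check, and no p-value is given. The arrays detected 11370 genes in P1, 11326 in P2, 11399 in P3 and 11424 in P4. The number of arrays limits the precision. A fold given as "at least" was bounded by the detection limit of 38.4 intensity units on the dimmer array. Some other folds rest on a dimmer array just above that limit and are close to such bounds. Among them are those of CUZD1 (41.7 in P4), RNU4ATAC (39.6 in P4), NDN (41.5 in P3) and ADM5 (39.6 in P1).

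In the widest passage comparison, P4 against P1, a run of neighbouring genes on the long arm of chromosome 20 was higher in P4, among them BCL2L1, which encodes the antiapoptotic protein BCL-XL and was 2.36-fold higher, and TPX2, a spindle assembly factor, 3.20-fold higher. Interferon-induced genes were also higher in P4, with IFIT2 at least 25.9-fold and IFIT1, which binds viral RNA, 14.4-fold higher. Detected in P1 and undetected in P4 was CHCHD2, a mitochondrial protein gene, with an intensity of 8230 in P1 and a level at least 214-fold lower in P4. The core pluripotency factors stayed within 2-fold, with POU5F1 1.33-fold higher, NANOG 1.04-fold lower and SOX2 1.07-fold lower in P4. In all, 215 genes were at least 2-fold higher and 146 at least 2-fold lower in P4, out of 11824 genes detected on at least 1 of these 2 arrays.

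Among genes measured on both arrays, IFIT1 was highest, followed by PKIB, an inhibitor of protein kinase A, at 6.91-fold higher in P4, and FOS, an immediate early transcription factor, at 6.48-fold. The long non-coding RNA LINC01139 was 5.67-fold higher, LCP1, an actin-bundling protein of blood cells, 5.55-fold, and CDX4, a caudal-type homeobox gene, 5.06-fold. INKA1, an inhibitor of the kinase PAK4, was 4.09-fold higher, the adhesion molecule CEACAM1 3.91-fold, the clustered protocadherin PCDHB3 3.68-fold and LEFTY1, a secreted inhibitor of nodal signalling, 3.51-fold. Besides IFIT2, genes undetected in P1 included the antisense transcript ZNF667-AS1 (at least 19-fold), IFIT3 (at least 10.4-fold), the zinc finger gene ZNF560 (at least 7.60-fold) and the secretory granule protein gene SCG2 (at least 7.57-fold).

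On the lower side, CUZD1 was 8.39-fold lower in P4 than in P1 and TEK, the angiopoietin receptor, 5.62-fold lower. Several small RNA genes stood among the lowest, though whether their probes read the mature small RNAs was not tested. The small Cajal body RNAs SCARNA8 and SCARNA13 were 5.22-fold and 5.13-fold lower, and RNU4ATAC, an RNA of the minor spliceosome, 4.16-fold. The U3 small nucleolar RNA copies SNORD3C, SNORD3A and SNORD3D were 3.56-fold, 3.50-fold and 3.42-fold lower, and as near-identical copies they may share probe signal. The lysosomal protease gene CTSF was 3.50-fold lower and the zinc finger gene ZNF138 3.44-fold lower. Besides CHCHD2, the genes undetected in P4 were led by CRYZ, a quinone oxidoreductase (at least 47.9-fold lower), ZNF680 (at least 16.5-fold), TRIM4 (at least 11-fold) and TYW3, an enzyme of transfer RNA modification (at least 8.92-fold). Of the 361 genes at least 2-fold different, 73 had another detected probe, which pointed the same way for 64, by at least 1.5-fold for 39, and the other way for 9; CHCHD2 and CRYZ each rested on a lone probe. The count was 635 with the floor at the 50th percentile, 195 with detection at the 75th percentile and 163 with an offset of 50 in place of the floor.

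**Figure D1:**
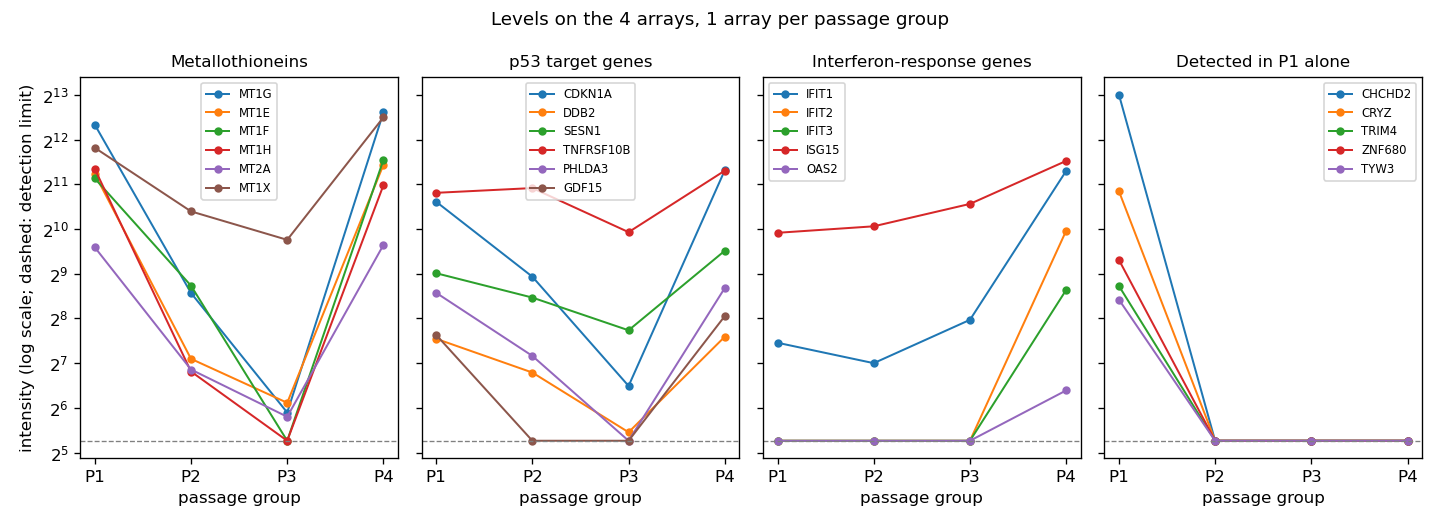
Intensity on a log scale (vertical axis) of named genes on the 4 arrays (horizontal axis, passage group), with 1 point per array and the detection limit of 38.4 dashed; undetected values are drawn at the limit. MT1G goes from 5158 in P1 to 59.5 in P3 and 6232 in P4, IFIT1 reaches 2519 in P4, and CHCHD2 lies at 8230 in P1 and under the limit elsewhere.

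Several genes of chromosome band 20q11.21, a region whose gain recurs in long-cultured human pluripotent stem cells, were higher in the later passage groups than in P1. The list of this band, fixed before the data were examined, had 16 detected members with a median log2 difference from P1 of 0.38 in P2, 0.95 in P3 and 1.25 in P4. In P2, 11 of the 16 were above 0 and none at least 2-fold higher. In P4 against P3 directly the median was 0.10, with 9 of 16 members above 0, none at least 2-fold higher and the upper limit of the random range at 0.098. The median in P4 against P1 lay at the 100 percentile of 10000 random lists matched on size and expression, a description of these arrays. In P4, 9 of the 16 members were at least 2-fold higher and none at least 2-fold lower than in P1. HM13, a signal peptide peptidase, was 3.27-fold higher, TPX2 3.20-fold, the kinesin gene KIF3B 3.09-fold and PDRG1 3.01-fold. The fold of HM13 rested on its brightest probe (log2 difference of 1.71), and its 2 other detected probes gave 0.57 and -0.28. The differentiation inhibitor ID1 was 1.91-fold higher in P4, and 1.03-fold higher in P3, while its dimmer detected probe read 40.8 in P1, 85.3 in P3 and 206.6 in P4, a log2 difference of 2.34. The de novo DNA methyltransferase DNMT3B was 1.27-fold higher in P4 and 1.13-fold lower in P3, and its dimmer detected probes gave log2 differences of 1.41, 0.38 and 0.29 in P4.

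Along the chromosome, the 14 detected genes from HM13 to COMMD7 had a median log2 difference from P1 of 0.61 in P2, 1.18 in P3 and 1.52 in P4. The ends of this run were chosen after the values were seen, so part of its contrast with the genes on either side comes from that choice. The 10 detected genes before HM13 had medians of 0.01, -0.02 and -0.29, and the 10 after COMMD7 had 0.03, 0.03 and -0.03. Within the run, POFUT1 read 1.14-fold lower and DUSP15 1.12-fold lower in P4, but POFUT1 was near the top of the scale, and another POFUT1 probe gave a log2 difference of 1.32. Lists of other regions, set beside it for comparison, lay near 0 in P4. Their medians were 0.07 for the short arm of chromosome 20, -0.01 for the rest of its long arm, 0.13 for the short arm of chromosome 12, 0.08 for the distal long arm of chromosome 17 and 0.03 for 1q32. The chromosome 12 list stood at the 97.3 percentile of its random lists, with LTBR 2.09-fold, ING4 1.85-fold, PTPN6 1.77-fold and TULP3 1.71-fold higher. With undetected members kept in, the 20q11.21 median was 0.00 in P4, because these members sit at the floor on both arrays.

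**Figure D2:**
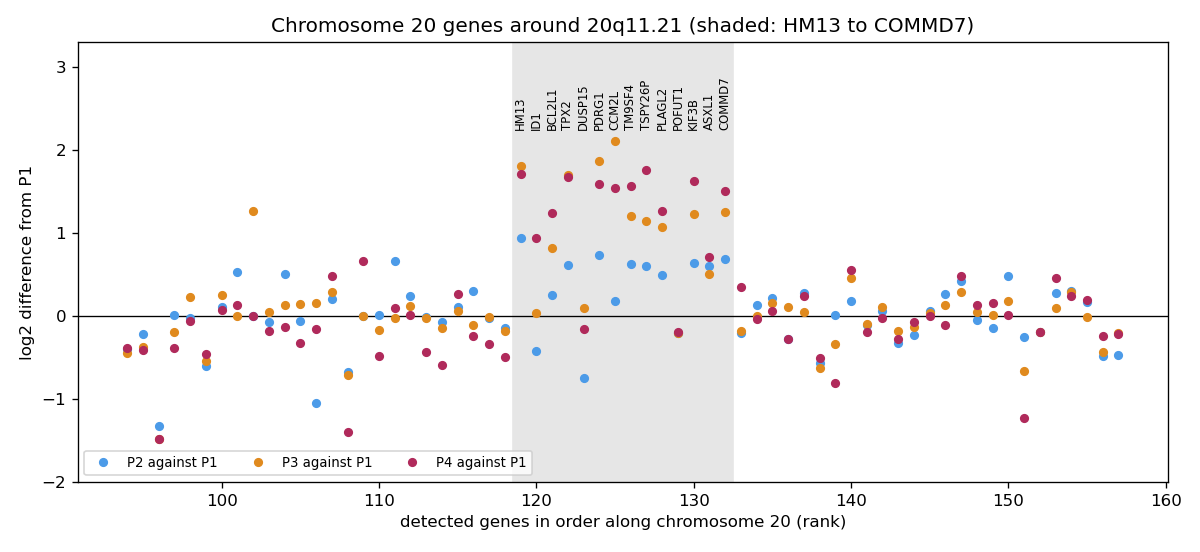
Log2 difference from P1 (vertical axis) of detected genes in their order along chromosome 20 (horizontal axis, rank), with 1 point per gene for P2, P3 and P4 and the genes from HM13 to COMMD7 shaded. The shaded genes have medians of 0.61 in P2, 1.18 in P3 and 1.52 in P4; the ends of the shading were chosen after the values were seen.

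Several other lists stood apart in P4 against P1. The interferon-response and HLA list had 25 detected members with a median log2 difference of 0.35, at the 99.98 percentile of random lists, and 5 members at least 2-fold higher; besides the IFIT genes, the ubiquitin-like modifier ISG15 was 3.05-fold higher. Fibroblast and extracellular matrix genes had a median of 0.53 over 15 members, with the galectin LGALS1 2.33-fold, the collagen gene COL1A1 2.03-fold, TIMP1 1.97-fold and COL5A1 1.79-fold higher. Immediate early genes had a median of 0.27 over 15 members, with FOS as above, EGR1 2.15-fold, JUN 1.69-fold and KLF6 1.65-fold higher. Hypoxia-induced genes had a median of 0.26, with the collagen hydroxylase P4HA2 1.85-fold, ADM 1.83-fold and BHLHE40 1.71-fold higher and MXI1 1.65-fold lower. Glycolysis genes had a median of 0.17, with PKM 1.43-fold, ALDOC 1.27-fold, PFKL 1.22-fold and GPI 1.21-fold higher.

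Mitosis and spindle genes had a median of 0.13 over 36 members, of which TPX2 alone was at least 2-fold higher, ahead of CENPE at 1.67-fold, INCENP at 1.48-fold and KIF2C at 1.48-fold. Without TPX2, its 20q11.21 member, the median was 0.12 and lay inside the random range, at the 95.6 percentile. The naive pluripotency list had 7 detected members, none at least 2-fold higher, a median of 0.49 and a mean of 0.17, and the naive median was 0.00 with no detection filter. KLF4 was 1.43-fold and KLF2 1.42-fold higher, TFCP2L1 at least 1.44-fold higher and DPPA5 at least 2.27-fold lower. Replication-dependent histone genes were the only list under its random range, with a median of -0.38 over 12 members, H2BC9 2.13-fold, H4C3 1.82-fold and H2AC18 1.80-fold lower and H2AC6 1.85-fold higher. In all, 8 of 43 lists lay above and 1 below the central 95% of their random lists. For lists of unrelated genes 2.15 would lie outside. Members of these lists can vary together and some lists share genes, so that number is no chance expectation for 2 single arrays. In P3 against P1, 9 lists lay above and 8 below.

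Core pluripotency genes stayed inside their random range in P4 against P1, with a median of 0.07 over 28 members, but 4 of them were at least 2-fold higher. These were LEFTY1, the nodal ligand NODAL (3.38-fold), LEFTY2 (2.35-fold) and UTF1 (2.16-fold), a chromatin factor of undifferentiated cells. The nodal and TGF-beta target list shared LEFTY1, NODAL and LEFTY2 and had a median of 0.15, with SMAD7 1.85-fold higher. Imprinted genes had a median of 0.11, with PEG3 undetected in P1 and at least 7-fold higher in P4. Genes reported to vary in silencing between pluripotent lines had a median of -0.30, at the 3.59 percentile, with CHCHD2 and TRIM4 as above and the antioxidant enzyme gene CAT at least 1.85-fold lower. In the Wnt list (median -0.14) AXIN2, a feedback inhibitor, was 2.30-fold higher, and in the BMP list (0.12) BMP2 was at least 3.01-fold lower.

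The medians of the remaining lists in P4 against P1 lay inside their random ranges. They were 0.01 for ectoderm, 0.16 for endoderm and 0.13 for trophoblast markers, 0.08 for antiapoptotic and -0.01 for proapoptotic genes, 0.09 for p53 targets and 0.21 for metallothioneins. DNA replication genes had -0.05, DNA repair genes 0.03, cyclin-dependent kinase inhibitors 0.05 and oxidative phosphorylation genes 0.02. Germline genes had 0.01, chromatin modifiers 0.03, HERV-H associated genes -0.34, stress response genes -0.03 and heat shock genes -0.03. Cholesterol synthesis genes had -0.01, YAP targets -0.01, epithelial and mesenchymal genes -0.01, ribosomal protein genes -0.04, drug transporters -0.14, housekeeping genes 0.02 and MYC-family and growth genes 0.09. The mean had the other sign for the ectoderm, oxidative phosphorylation, chromatin, HERV-H, stress response, cholesterol, BMP, epithelial, proapoptotic, housekeeping and MYC-family lists. The mesoderm list had only KDR (1.36-fold higher) and BMP4 (at least 1.27-fold lower) detected and received no median.

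**Figure D3:**
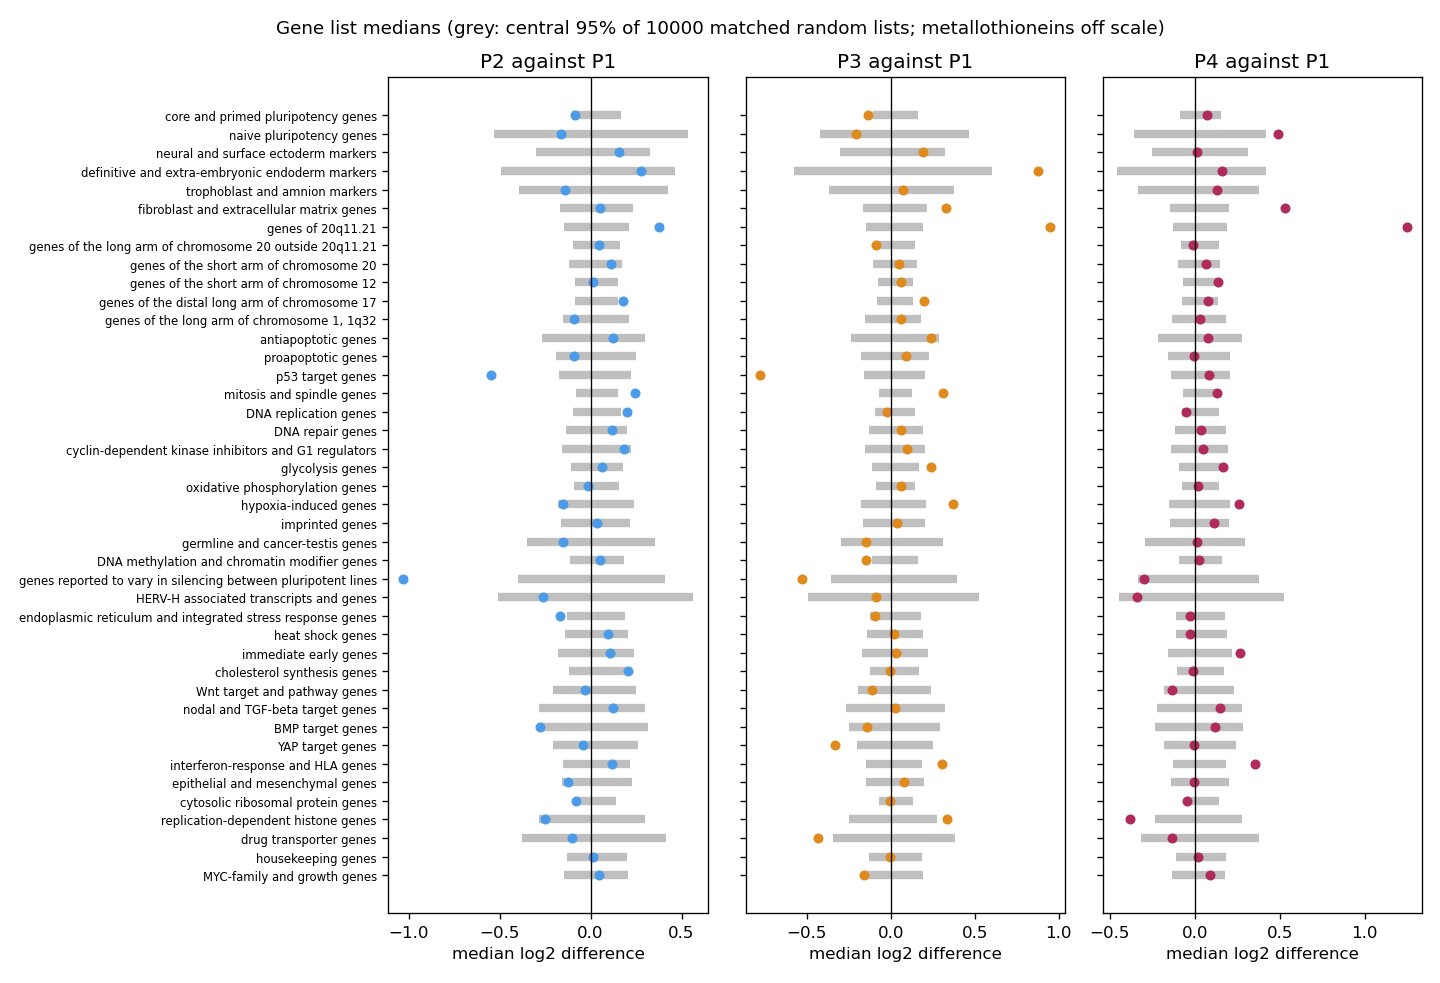
Median log2 difference from P1 (horizontal axis) of each gene list (vertical axis) in P2, P3 and P4, with 1 point per list and grey bars for the central 95% of 10000 matched random lists; metallothioneins are not drawn. The 20q11.21 list lies at 0.38, 0.95 and 1.25, and the p53 target list at -0.55, -0.78 and 0.09.

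In P2 against P1, the imprinted gene NNAT, which encodes neuronatin, was 40.5-fold lower in P2, from an intensity of 2130 to 52.5. The metal-binding metallothioneins MT1H, MT1E and MT1G were 23.1-fold, 17.5-fold and 13.6-fold lower, and ECHDC3, a mitochondrial hydratase-related gene, 9.24-fold lower. On the higher side were PKIB at 6.71-fold, ADM5 at 4.98-fold, CHODL at 4.81-fold, MIR124-1HG, the host transcript of a neural microRNA, at 4.37-fold and the tumour suppressor RASSF1 at 4-fold. CHCHD2, CRYZ, ZNF680, TRIM4 and TYW3 were already undetected in P2, and SCG2, undetected in P1, was at least 13-fold higher.

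Counts in P2 against P1 were 257 genes at least 2-fold higher and 257 lower, of 11807 detected. All 7 detected metallothioneins were at least 2-fold lower, with a median log2 difference of -2.73, and 3 of 22 p53 targets were lower, with a median of -0.55. Genes reported to vary in silencing had 4 of 8 members at least 2-fold lower and a median of -1.03. These medians lay at the 0 percentile of random lists. Stress response genes (-0.17) and ribosomal protein genes (-0.08) also lay under their random ranges. Mitosis and spindle genes had a median of 0.25, DNA replication genes 0.20, cholesterol synthesis genes 0.21 and the chromosome 17 list 0.18, each above its random range. POU5F1 was 1.07-fold higher, NANOG 1.35-fold lower and SOX2 1.05-fold lower. The comparisons against P1 share that array, so a P1 level of its own enters each of them.

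In P3 against P1, metallothioneins and targets of the tumour suppressor p53 were lower in P3. MT1G was 86.6-fold, MT1E 34.7-fold and MT2A 13.8-fold lower, and MT1H and MT1F, undetected in P3, were at least 67.6-fold and at least 58.3-fold lower. CDKN1A, the cell cycle inhibitor p21 and a p53 target, was 17.4-fold lower, and the imprinted gene NDN, which encodes necdin and has a lone probe here, 59.9-fold lower. LCP1 was 85.9-fold higher, with an intensity of 8826 in P3, and the cancer-testis antigen gene MAGEA4 13.1-fold higher. RASAL3 was 9.10-fold, STMN2, a neuronal tubulin-binding protein, 9.06-fold and FOS 6.93-fold higher. ECHDC3 was at least 26.5-fold lower and ATP8B3, undetected in P1, at least 5.27-fold higher.

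Counts in P3 against P1 were 231 genes at least 2-fold higher and 188 lower, of 11844 detected. All 7 metallothioneins were at least 2-fold lower, with a median log2 difference of -5.12, and as members of a multigene family their probes may share signal. Of 22 p53 targets, 8 were at least 2-fold lower and none higher, with a median of -0.78; the lower members included PHLDA3 and DDB2, a damage-binding repair protein, at log2 differences of -3.31 (a bound) and -2.09. Both medians lay at the 0 percentile of random lists. Mitosis genes had a median of 0.31, with 35 of 36 above 0, fibroblast genes 0.33, hypoxia-induced genes 0.37, glycolysis genes 0.24 and interferon-response genes 0.30, each above its random range. YAP targets had -0.34 and core pluripotency genes -0.14, both under theirs, with POU5F1 1.33-fold higher, NANOG 1.38-fold lower and SOX2 1.11-fold lower.

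In P3 against P2, NNAT was 73.7-fold higher in P3 and LCP1 27.1-fold higher. TXNIP, a thioredoxin-binding protein, was 10.8-fold higher, the splicing regulator MBNL3 10.7-fold and the histone gene H2AC6 6.14-fold. NDN was 65.2-fold lower, MT1G 6.38-fold, CDKN1A 5.44-fold, RIPOR2 4.18-fold and ENTREP1 3.69-fold lower. Genes undetected in P3 included PYCR1, an enzyme of proline synthesis (at least 20.6-fold lower), the iron oxidase HEPH (at least 12.7-fold), MT1F (at least 11.1-fold), COMMD8 (at least 10.4-fold) and the DNA repair enzyme gene MGMT (at least 6.54-fold). MAGEA4, undetected in P2, was at least 16.0-fold higher in P3. In all, 246 genes were at least 2-fold higher and 124 lower, of 11777 detected. TPX2 was 2.12-fold and BCL2L1 1.48-fold higher, and the p53 target list had a median log2 difference of -0.46.

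In P4 against P3, metallothioneins, NDN and CDKN1A, which were low in P3, were higher in P4. MT1G was 105-fold, MT1E 40.0-fold and MT2A 14.3-fold higher in P4, MT1F and MT1H at least 77.8-fold and at least 52.5-fold higher, NDN 70.3-fold and CDKN1A 28.3-fold. PYCR1 and MGMT were at least 25.8-fold and at least 19.9-fold higher, and IFIT2 at least 25.9-fold higher. LCP1 was 15.5-fold lower, MAGEA4 12.6-fold, CUZD1 7.57-fold, the mucosal peptide gene TFF3 5.11-fold and RASAL3 3.99-fold lower, and the relaxin gene RLN2, undetected in P4, at least 6.12-fold lower.

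Of 11780 detected genes, 157 were at least 2-fold higher and 90 lower in P4 than in P3, the smallest total of the 5 planned pairs. The p53 target list had 10 of 22 members at least 2-fold higher and a median log2 difference of 0.96, and the metallothionein list had 6 of 7 higher and a median of 5.32, both at the 100 percentile of random lists. Histone genes had 6 of 11 members at least 2-fold lower and a median of -1.01, and mitosis genes a median of -0.16 with 5 of 36 above 0. Both medians lay at the 0 percentile. In P3 against P1 the histone median was 0.335, above its random range, so a high P3 level enters this fall. BCL2L1 was 1.33-fold higher, ID1 1.87-fold, DNMT3B 1.44-fold and NANOG 1.33-fold, with TPX2 1.01-fold lower.

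Through the passage order P1, P2, P3, P4, CDX4 was higher at each step and reached 5.06-fold, from an intensity of 71.2 to 360.3. INKA1 (4.09-fold), PCDHB3 (3.68-fold), TSPY26P, a pseudogene inside the 20q11.21 run (3.38-fold), and the potassium channel gene KCNF1 (3.17-fold) did the same. TEK was lower at each step, to 5.62-fold, as were the potassium channel gene KCNG3 (3.07-fold), DST, a cytoskeletal linker gene (2.72-fold), SNORD12C (2.69-fold) and SCARNA14 (2.68-fold). A step of any size counted. CDX4 read 71.21, 248.6, 328.2 and 360.3, PCDHB3 42.39, 45.98, 53.15 and 156.1, and KCNG3 262.2, 99.33, 92.85 and 85.29. Most of each of these changes fell in 1 step. In all, 53 genes stepped up and 46 stepped down with a total of at least 2-fold. In the simulated arrays, which held no trend but some genes changed in P4, 31 genes stepped one way. The passage order ranked 5 of the 12 possible orders of the arrays, behind the order P1, P4, P3, P2, with 167 such genes. This rank compares orders with unlike ends, since the 2-fold total is taken between the end arrays. P2 against P1 had 514 genes at least 2-fold different and P4 against P1 had 361. The other order with ends P1 and P4, which is P1, P3, P2, P4, gave 63.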

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

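Probes without a single gene name were used in no comparison of the report. Of 17210 such probes, 4428 were detected in P4 or P1, and of these 63 were at least 2-fold higher in P4 and 77 at least 2-fold lower, which drew attention as signal in values outside the named genes. Among named genes in P4 against P1, 361 of 11824 detected were at least 2-fold different, or 3.05%, a share near that of these probes. The same count of probes gave 98 higher and 60 lower in P2 against P1.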

How the results depend on the processing

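The deposited values without normalization, the offset of 50 and the lists set outside P4 against P1 were chosen after the data were seen, as was the rule for calling a list median moved. That rule is a shift larger than the reach to either side of the central 95% of random-list medians; it replaced a rule of 1 SD after the number of moved values was seen, and 38 of 469 list values moved under it, against 81 under the rule of 1 SD. No called value reversed. Centring, the deposited values, the mean of all probes and no detection filter each left all 6 counts within 1.5 times, the last by construction. Centring came after quantile normalization and its shifts ran only from -0.019 log2 in P1 to 0.014 in P4, so it does not test that normalization. Among single named genes, 56 of 990 values moved. No paired analysis was possible because each group had 1 array. Signal over background limits the low genes, where the floor sets the counts. The causes were not tested, except that a looser or stricter threshold, filter or floor admits more or fewer genes by construction.

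Genes at least 2-fold different numbered 514, 419, 361, 370 and 247 in P2 against P1, P3 against P1, P4 against P1, P3 against P2 and P4 against P3, and 99 stepped one way. In that order, detection at the 75th percentile gave 267, 226, 195, 205 and 142, with 61 stepping. A threshold of 1.5-fold gave 1867, 1606, 1452, 1398 and 919, with 347 stepping, and 3-fold gave 84, 89, 76, 85 and 72, with 18 stepping. A floor at the 50th percentile gave 846, 734, 635, 619 and 441, with 152 stepping, and an offset of 50 gave 222, 196, 163, 208 and 147, with 51 stepping. Without P2, 231 genes stepped, and without P3, 220, since fewer steps are asked for. The share stepping up was 53.5%, and 41.8% with centring, 42.9% at 1.5-fold, 83.3% at 3-fold and 66.7% with the offset. The share higher was 63.6% in P4 against P3, and 77.8% at 3-fold and 75.5% with the offset; in P3 against P2 it was 66.5%, and 55.9% at 1.5-fold.

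With no detection filter, which adds members held at the floor, the 20q11.21 median was 0.000 in P4 against P1, 0.000 in P2 against P1, 0.003 in P3 against P1 and 0.002 in P3 against P2. The same setting in P4 against P1 gave 0.000 for naive pluripotency, 0.237 for fibroblast and 0.015 for chromosome 12 genes. It gave metallothionein medians of -4.453 in P3 against P1 and 4.583 in P4 against P3, and 0.827 for p53 targets in P4 against P3. Means in place of medians gave 0.272 for pluripotency, 0.928 for 20q11.21, -1.515 for variably silenced, 0.527 for immediate early, 0.479 for nodal target and 0.816 for interferon genes in P4 against P1. Means were -4.340 and 4.513 for metallothioneins and -1.041 and 1.190 for p53 targets in P3 against P1 and P4 against P3. Detection at the 75th percentile gave -0.518 for germline, -1.952 for variably silenced and 0.283 for Wnt genes in P4 against P1, and -5.491 for metallothioneins in P3 against P1. The germline and Wnt medians changed sign from 0.015 and -0.135, neither outside its random range. The mean of all probes gave 0.426 for nodal targets and -0.123 for MYC-family genes in P4 against P1, and 4.748 for metallothioneins in P4 against P3. The offset gave -4.362 and 4.565 for metallothioneins in P3 against P1 and P4 against P3, and 0.826 for p53 targets in P4 against P3.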

Other observations

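Every test in this part was chosen after the result it bears on was seen. Some genes stood at least 2-fold above or below each of the other 3 arrays, 43 higher and 7 lower in P4, and 43 higher and 41 lower in P1, the most of any array. Those of P1 include PKIB, SCG2, CDX4, LEFTY1, SCARNA8 and SNORD3A, so their differences in P4 against P1 rest on the P1 array as well. Genes apart in P4 included further interferon-induced genes, with MX2 2.99-fold, HERC5 2.53-fold, IFIH1, a sensor of double-stranded RNA, 2.30-fold and OAS2 at least 2.18-fold above the nearest of the other arrays. Folds in this paragraph are likewise against the nearest array. The imprinted gene PEG3 and its neighbour ZNF667 were at least 7-fold and at least 6.54-fold higher than on any other array. In P3, 32 genes were higher and 27 lower than on each other array, among them TFF3 (4.28-fold higher) and the p53-linked genes TRIM22 and DRAM1 (at least 4.27-fold and 3.03-fold lower). In P2, 22 were higher and 53 lower, with the neural transcription factor gene SOX21 2.66-fold and the retinoic acid hydroxylase CYP26A1 2.30-fold higher, and NNAT 29.9-fold, MBNL3 3.84-fold and SOX3 2.46-fold lower.

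Windows of 15 neighbouring detected genes also stood out away from chromosome 20. The clustered protocadherins from PCDHA2 to PCDHB18P had a median log2 difference of 0.88 in P4 against P1, and all 18 detected ones had 0.46, with near-identical family members that may share probe signal; the largest window median in shuffled gene orders was 0.59, and 20q11.21 reached 1.503. On chromosome 3, the window from ARL6IP5 to CGGBP1 had -0.73 in P4 against P1 and -0.55 in P4 against P3. On chromosome X, 6 windows were higher in P4 against P1, from 0.61 to 0.99, the last from HDAC6 to PRICKLE3. In P3 against P1, 3 windows of X were higher, up to 1.14 from PQBP1 to CCDC22, near the 1.15 of 20q11.21. In P2 against P1, 2 were higher (0.69 and 0.66) and 2 lower, from BCORL1 to GPC4 (-0.82) and from MID2 to DCX (-0.78). Small RNA genes, 129 detected, had a median of -0.30 in P4 against P1 with 19 at least 2-fold lower and 4 higher, below the random range. Whether their probes read the mature small RNAs was not tested. They had -0.14 in P3 against P1, also below it, but 0.08 in P2 against P1, inside it, with 20 at least 2-fold higher and 16 lower.

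The 20q11.21 genes were higher in P4 than in P1 by a median of 1.25. Array-wide normalization is argued against by the other genes of 20q, with a median of -0.012, and a larger share of mitotic cells by the mitosis list without 20q11.21 members, with 0.119. The highest of all windows in P4 against P1 lay on this region at 1.503, but 14 of its 15 genes are members of the list, so it restates the list's median, and a gain of the region is left open. In P3 a window on chromosome X was about as high, at 1.141 against 1.147, so a run moving together was not limited to this region. DNA copy number was not measured here, and passage group, carried by 1 array each, stays an untested explanation.

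Metallothioneins and p53 target genes were lower in P3 than in P1 or P4, and less far lower in P2, with medians against P1 of -2.73 and -0.55, so a cause in P3 alone would leave P2 unaccounted for. A poor P3 array is argued against by the SD over genes of the log2 difference in P4 against P3, which at 0.346 was the smallest of all pairs. Probes all reading 1 shared metallothionein transcript would keep their order of brightness on each array, and the values argue against this. MT1G read above MT1F in P1 (5158 and 2242) but below it in P2 (379.7 and 425.1). MT1H read above MT1F in P1 (2597) but below it in P2 (112.4) and in P4 (2018 and 2989). Partly shared signal is left open. In P4 against P3, the log2 differences spanned 3.97 over the 4 members detected in P1, P3 and P4, which does not decide this. But MT1G, MT1E and MT2A read only 59.5, 69.2 and 55.7 in P3, near the limit, so unequal probe brightness on 1 transcript could give such a span. P3 coming from other cells than P4 is left open: the 4 genes above 10 times the limit in P1 and undetected in P4 were all undetected in P3, but 6 genes above 10 times the limit in P1 and P4 were undetected in P3 alone of these 3. They include PYCR1, MGMT, PABPC4L and HEPH besides MT1F and MT1H, so other cells, a sister culture or a culture state of the harvested P3 cells could each remain, with 4 shared losses.

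CHCHD2, CRYZ, TRIM4 and ZNF680 were undetected in P2, P3 and P4, the 4 genes above 10 times the limit in P1 that were. Lower sensitivity of the 3 later arrays is argued against, since it would take dimmer genes first, and of 4239 genes between 2 times the limit and the dimmest of these 4 in P1, 97.7% stayed detected on all 3. Loss of the region around TRIM4 is argued against by its 20 nearest detected neighbours, with a median of 0.043 and none 2-fold lower, though a loss of TRIM4 alone is not. Around the other 3 genes it is left open, with medians of -0.25 at CHCHD2, -0.217 at ZNF680 and -0.093 at CRYZ. Only 2 of 20 neighbours were at least 2-fold lower at CHCHD2 and at ZNF680, which are ZNF138 and each other. At CRYZ only 1 of 20 was, which is TYW3. Neighbours were taken by order among detected genes, without regard to distance. A separate lineage of the P1 culture cannot be told apart from passage with 1 array per group, and these 4 genes could reflect either.

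For the order of passages, 99 genes stepped one way, 5 of the 12 orders gave at least as many, the highest other order gave 167, and 12 orders are too few for a share under 5%. Orders with unlike end arrays are not on equal terms, and the other order with ends P1 and P4 gave 63.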
